A study of Arabidopsis thaliana with 10 samples.

How the data were processed

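The data were 10 arrays of 12-day-old Arabidopsis thaliana seedlings from 5 lines, 2 arrays per line: VC, Col-0, FL3, dC26 and dC27. Per the labels' protocols, total RNA was extracted with Trizol, amplified and labelled with biotin, and hybridised to Affymetrix arrays. The deposited values are intensities on a linear scale, one per probe set and array, judged from the values themselves, which ran from 3.68 to 12648. The summary and normalization the authors used to make these intensities, and the software, are not given in the sources used here. Medians of log2(value + 16) lay between 5.85 and 5.91 over the arrays. How the values were scaled and how background was handled stay unknown. No raw scanner values were used here.

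The table held 22810 probe sets. The 64 control probe sets were left out of all tests, which leaves 22746. The platform annotation listed 1 gene for 13513 of the tested probe sets, several for 503 and none for 8730. Of those with 1 gene, 13436 were matched through the gene identifier to a locus of the TAIR10.1 gene table, 13286 distinct loci, which were the background for gene lists. Probe sets with several genes or none are not named by gene. Names come from these tables alone, and many well-known genes had no named probe set there: of 462 genes in the 29 lists fixed beforehand, 59 had one, 7 lists had none and 12 lists had at least 3 and were tested as sets. These were auxin response, cell wall loosening, cold-regulated genes, flavonoid and anthocyanin synthesis, heat shock, jasmonate response, mitochondrial retrograde response, photosynthesis, reference genes, root markers, senescence and unfolded protein response. In addition, 21 gene families defined by gene symbol were chosen after seeing the annotation, before any comparison was computed. No coordinates are given.

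Intensities were transformed as log2(value + 16), a pseudocount planned for linear values. Of all values 34.8% were below 16, so a log2 change understates the change of dim probe sets, and folds given here are on that scale. limma 3.58.1 in R 4.3.3 fitted a mean for each of the 5 lines over all 10 arrays (5 residual degrees of freedom), with moderated variances and an intensity trend, two-sided tests and Benjamini-Hochberg adjustment over the 22746 probe sets within each contrast, at a threshold of 0.05. Contrasts were FL3, the mean of dC26 and dC27, dC26 and dC27 each against the mean of VC and Col-0; FL3 against the mean of dC26 and dC27; dC26 against dC27; and VC against Col-0. The lines share 1 estimate of the spread, and with 2 arrays per line the number of arrays limits the precision. Figures were drawn with matplotlib 3.10.9.

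Gene lists were tested with camera at a preset inter-gene correlation of 0.01, again with the estimated correlation, and with fry. Adjustment was over the lists within a contrast. Single members were counted over all probe sets and adjusted over the list alone, and a gene with several probe sets was represented by the brightest. None of the list calls at the preset correlation held with the estimated one. The genes named were, for FL3 against controls, dC lines against controls and FL3 against dC lines, the 10 largest rises and falls among probe sets past the threshold, with exactly 1 gene, whose arrays did not overlap between the 2 sides; for other contrasts the 5 largest; and from each list the up to 4 members with the largest change among those past the threshold over all probe sets or over the list alone. All this was fixed before the data were examined. Where fewer passed, all were named. Members of lists that did not pass are named as background.

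Contrasts that share controls were compared with 50 simulations of unchanged groups, with the overlap of independent lists and with separate control lines. Further data were simulated with changes placed only among brighter, independent probe sets, alike in FL3, dC26 and dC27. Changes in dim probe sets, or differing between dC26 and dC27, were not covered. The fit was tested on these further simulated data. Of 100 probe sets changed by a log2 value of 1 it recovered 80 for FL3 against controls, 92 for the dC lines, 79 for dC26 and 83 for dC27, and of 100 changed by 2 it recovered 98, 100, 99 and 99, with 4 to 11 false calls among 22746. Alternatives chosen beforehand were a replicate block, quantile normalization, median centring, removal of the probe sets with the lowest mean (15164 left), a variance prior without a trend or robust, pseudocounts of 1 and 64, each control line alone, a 2-group fit, a 2-fold minimum and leaving out each array in turn. The 2-group fit took the arrays of each side as replicates, so differences between lines of a side entered the spread. No pseudocount, leaving out both dC27 arrays and leaving out dC26 replicate 2 with dC27 replicate 1 were chosen after seeing the data.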

Results

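Gene expression was measured on Affymetrix arrays in Arabidopsis thaliana seedlings harvested at 12 days of age from 5 lines, with 2 arrays per line and 10 arrays in all. FL3 expressed the full-length form of the transgene TaSIN, and dC26 and dC27 (ΔC26 and ΔC27 in the labels) were 2 lines expressing a shorter TaSIN from which the transmembrane motif had been removed. The controls were VC, a line transformed with an empty vector, and Col-0, the untransformed wild type. The 2 arrays of a line were described by the submitters as biologically independent. Array medians of the deposited intensities lay between 41.8 and 44.3. Replicate arrays correlated across probe sets at 0.991 in VC, 0.991 in Col-0, 0.993 in FL3, 0.986 in dC26 and 0.971 in dC27. With an array of another line dC26 replicate 1 correlated at up to 0.9887, against 0.9856 with its own replicate. The same held for dC27 replicate 1 and 2, at 0.9709 and 0.9825 against 0.9707, and for no other array. The SD of the log2 difference between the 2 arrays of a line was 0.206 in FL3, 0.236 in VC, 0.235 in Col-0, 0.293 in dC26 and 0.415 in dC27. No probe set was named for TaSIN in the annotation used here, so the level of the transgene was not measured.

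The first comparison asked which genes respond to full-length TaSIN in seedlings grown without stress. The largest rise, on the scale of log2(intensity + 16) used throughout, was that of AT2G21640 (UPOX, a nuclear gene induced by oxidative stress and mitochondrial dysfunction), from an intensity of 42.7 over the 4 control arrays to 2059 ± 22.4 (SD, n = 2) in FL3, which is 36.0-fold or 5.17 ± 0.18 (SE) on the log2 scale. AT2G04050, which encodes a MATE-type efflux transporter, rose by 4.88 ± 0.14 from 17.5 to 967, and AT2G18190, which encodes an AAA-type ATPase, rose by 4.24 ± 0.25 from 8.89 to 453. The control levels of AT2G04050 and AT2G18190 lie near the lower end of the scale, where the pseudocount limits a log2 change, so these 3 genes were not ranked beyond this scale. AT5G51440, a mitochondrial small heat shock protein, rose by 3.04 ± 0.26. The falls were smaller: AT1G66100, which encodes a thionin-type antimicrobial peptide, fell by 1.83 ± 0.21 on the log2 scale, from 209 to 47.8.

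In all, 611 of 22746 probe sets differed between FL3 and the controls, 500 higher and 111 lower (limma, Benjamini-Hochberg adjusted p under 0.05), and 114 of them changed at least 2-fold. The other rises among the 10 largest were those of AT2G20720 by 3.60, AT2G32020 by 2.86, AT2G41730 by 2.56, AT5G46710 by 2.30, AT5G40690 by 2.04 and AT3G45730 by 1.999 on the log2 scale. AT2G32020 encodes an acetyltransferase of the GNAT type, and AT5G46710 a PLATZ-type zinc-finger protein. The other large falls were those of AT1G19540 (log2 change -1.39), the plant defensin gene PDF1.4 (-1.08), AT1G78450 (-1.01), AT1G72060 (-1.004), UGT72E1 (-0.95), a glucosyltransferase of the monolignol pathway, AT4G37220 (-0.94), AT1G68585 (-0.93), AT3G16800 (-0.93) and AT3G61160 (-0.92). Adjusted p ranged from 4.9e-07 for AT2G04050 to 0.034 for AT3G16800 over these 20 genes (limma, Benjamini-Hochberg). Of the 611 probe sets, 343 were paired with a single gene by the annotation, 288 of them higher and 55 lower.

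Among the gene lists fixed beforehand, the mitochondrial retrograde response moved up in FL3 as a set (camera, adjusted p = 8.2e-06), but not with an estimated correlation between genes (adjusted p = 0.33). Of its 4 named members, AT2G21640 rose over all probe sets tested. Adjusted over the list alone, 3 of the 4 passed. Besides AT2G21640 these were GSTU25, a tau-class glutathione S-transferase, with a log2 change of 1.495, and NDB2, an alternative mitochondrial NADH dehydrogenase, with 0.62. The FL3 arrays differed widely in GSTU25, at 235 ± 200 (SD, n = 2) against 62.9 ± 43 in Col-0. GSTU25 did not pass over all probe sets (limma, Benjamini-Hochberg adjusted p = 0.15). AT5G09570 (At12Cys), a cysteine-rich mitochondrial protein, had a log2 difference of 0.58 ± 0.33 that did not pass. COR15A, a cold-induced chloroplast protein, fell by 0.89 on the log2 scale, while COR15B, COR47 and LTI30 of the same list had log2 differences of 0.18, -0.27 and 0.21 that did not pass. The call of COR15A ended without either VC array, Col-0 replicate 1 or either FL3 array. The jasmonate-responsive defensin genes PDF1.2 and PDF1.2b had log2 differences of -1.36 and -1.78 that did not pass over all probe sets (limma, Benjamini-Hochberg adjusted p = 0.054 and 0.057). Both passed when adjusted over the list alone. The jasmonate list did not pass as a set (camera, adjusted p = 0.14). Adjusted over the list alone, 1 of 3 auxin genes passed, WES1 with -0.63, and 3 of 3 cell wall loosening genes, XTH33 with -0.88, EXPA8 with -0.67 and EXPA4 with 0.37. Neither list passed as a set (camera, adjusted p = 0.25 and 0.26). In the list of photosynthesis genes 0 of 4 members passed, with differences from -0.18 for LHCB4.1 to 0.17 for RCA. The same held for root markers (0 of 3), heat shock (0 of 4), senescence (0 of 3), unfolded protein response (0 of 5), flavonoid synthesis (0 of 4) and reference genes (0 of 4), over all probe sets by limma and over each list alone. At an unadjusted p under 0.05, 3000 probe sets differed in this contrast, and the test by fry of change in either direction gave an unadjusted p between 0.13 and 0.98 in those 7 lists.

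Calls in FL3 rested on both of its arrays: without FL3 replicate 1 or 2 the count was 57 or 79, and it was 279 without VC replicate 1, 397 without VC replicate 2, 231 without Col-0 replicate 1 and 376 without Col-0 replicate 2. It was 391 against either control line alone. Of the 10 largest named rises 7 passed whichever array was left out, and of the 10 largest named falls 1 did, AT1G19540. In a 2-group fit 686 probe sets passed in FL3, but AT1G72060, PDF1.4 and COR15A did not (limma, adjusted p = 0.074, 0.14 and 0.071). Its spread included that between VC and Col-0. FL3 is 1 line, so spread between TaSIN lines was not included.

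**Figure D1:**
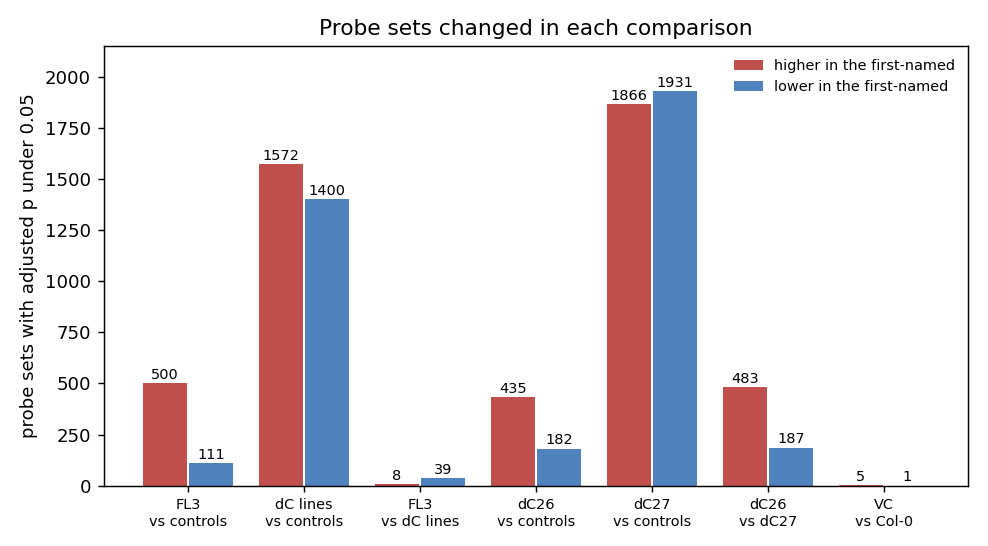
Number of probe sets (vertical axis) past an adjusted p of 0.05 in each of 7 comparisons, split into those higher (red bars) and lower (blue bars) in the first-named line or lines. FL3 differed from the controls by 500 rises and 111 falls, dC27 by 1866 rises and 1931 falls, and VC from Col-0 by 5 and 1.

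The second comparison set both lines with truncated TaSIN against the same controls. The gene with the largest rise was again AT2G21640, by 5.21 ± 0.14 on the log2 scale, to 1846 ± 44.1 in dC26 and 2428 ± 235 in dC27 (SD, n = 2 each). AT2G04050 rose by 4.44 ± 0.12 and AT2G18190 by 3.90 ± 0.21. A pair of tau-class glutathione S-transferase genes rose strongly: GSTU22 by 3.61 ± 0.21, from 122 to 1663, and GSTU25 by 2.92 ± 0.37, from 60.6 to 545. IAA29, an Aux/IAA repressor of auxin signalling, fell from 274 to 83.9, a log2 change of -1.63 ± 0.28.

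The count was 2972 probe sets, 1572 higher and 1400 lower, with 346 changed at least 2-fold (limma, Benjamini-Hochberg adjusted p under 0.05). Completing the 10 largest rises were AT2G32020 (3.62), AT2G20720 (3.59), AT5G51440 (2.98), AT1G17960 (2.93), which encodes a threonyl-tRNA synthetase, and AT5G56350 (2.37), which encodes a pyruvate kinase. The 10 largest falls, with IAA29, were AT1G10340 (-1.96), an ankyrin-repeat protein gene, GAT1_2.1 (-1.91), which encodes a class I glutamine amidotransferase-like protein, AT1G19540 (-1.88), AT1G72060 (-1.85), AT1G54740 (-1.83), AT3G20340 (-1.82), AT3G62950 (-1.78), a glutaredoxin-type gene, AT1G62510 (-1.57) and AT1G19960 (-1.53). All 20 passed whichever array was left out. When the spread included that between lines, AT1G62510 and AT1G19960 did not pass (adjusted p = 0.07 and 0.056). In dC26 alone neither passed (adjusted p = 0.19 and 0.086), and nor did IAA29 (0.086), AT3G20340 (0.064), AT3G62950 (0.10) or, by a narrow margin, GAT1_2.1 (rounded to 0.05). The other 4 falls passed.

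The mitochondrial retrograde list moved up in the dC lines (camera, adjusted p = 4.8e-07), and all 4 of its named members rose over all probe sets: AT2G21640, GSTU25, AT5G09570 by 1.91 ± 0.27 and NDB2 by 1.06 ± 0.18. With an estimated correlation the adjusted p was 0.12. The auxin response list moved down (camera, adjusted p = 3.4e-05, and adjusted p = 0.12 with an estimated correlation), and all 3 of its named members fell. Besides IAA29 these were WES1 (log2 change -1.39 ± 0.12) and GH3.3 (-1.05 ± 0.13), which encode enzymes that conjugate auxin to amino acids. GH3.3 did not pass when the spread included that between lines (adjusted p = 0.078). In dC26 alone GH3.3 and NDB2 did not pass (adjusted p = 0.095 and 0.079). The jasmonate list moved down (camera, adjusted p = 0.018, and adjusted p = 0.35 with an estimated correlation), with falls of PDF1.2b (-1.92 ± 0.34) and PDF1.2 (-0.88 ± 0.25) and a log2 difference of -0.17 in THI2.1 that did not pass. The PDF1.2b change was -3.34 in dC27 and -0.49 in dC26, where it did not pass (adjusted p = 0.59), and its call ended when the spread included that between lines (adjusted p = 0.14). PDF1.2 changed by -1.59 in dC27, with a difference of -0.17 in dC26 that did not pass (adjusted p = 0.83). Whether the probe sets of PDF1.2 and PDF1.2b each read only their own gene was not tested, so they may not be independent members. The jasmonate list's call ended without Col-0 replicate 2 or dC26 replicate 1 (adjusted p = 0.06 each), and that of PDF1.2 itself without any 1 of 8 arrays, all but VC replicate 1 and Col-0 replicate 1. Adjusted over the list alone, the counts were the same, 4 of 4, 3 of 3 and 2 of 3.

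The remaining lists did not pass as sets in the dC lines by camera (adjusted p from 0.064 to 0.96). The test by fry of change in either direction gave an unadjusted p of 0.0041 for photosynthesis genes, 0.0051 for cold-regulated genes, 0.017 for the unfolded protein response and 0.056 to 0.99 for the other 6. In the cold-regulated list LTI30, a dehydrin, rose by 1.00 ± 0.27 and COR15A fell by 0.88 ± 0.13. In the cell wall loosening list the expansin EXPA4 rose by 0.47 ± 0.12, EXPA8 fell by 1.17 ± 0.21 and XTH33 had a log2 difference of -0.48 that passed over the list alone. In the heat shock list AT5G48570 (ROF2), a heat-induced immunophilin, rose by 0.80 ± 0.16, with a rise of 1.475 in dC26 and a difference of 0.13 in dC27 that did not pass. In the unfolded protein response list CRT1b, a calreticulin, rose by 0.48 ± 0.13 and the co-chaperone ATERDJ3B passed over the list alone, with 0.31. LEA4-5, a late embryogenesis abundant protein and 1 of 2 named genes of the ABA and drought list, rose by 0.66 ± 0.08 from 12.3 to 28.8. Photosynthesis genes (0 of 4), senescence genes (0 of 3), flavonoid genes (0 of 4) and reference genes (0 of 4) had no member past the threshold over all probe sets or over the list alone, and root markers had EXPA18 past it over the list alone, with 0.52 at intensities of 20.4 and 36.9. In this contrast 6263 probe sets had an unadjusted p under 0.05. The calls of LTI30, EXPA4 and CRT1b ended without 1 of 6, 4 and 8 of the arrays, and those of COR15A, EXPA8, AT5G48570 and LEA4-5 held whichever array was left out. When the spread included that between lines EXPA8 and LEA4-5 passed, while COR15A, AT5G48570, LTI30, EXPA4 and CRT1b did not (adjusted p = 0.083, 0.19, 0.061, 0.24 and 0.085). The call of COR15A also ended against VC alone. In dC26 alone COR15A, EXPA8, LTI30, EXPA4 and CRT1b did not pass (adjusted p = 0.16, 0.17, 0.24, 0.78 and 0.21). COR15B passed there, with a log2 change of 0.998 (limma, adjusted p = 0.043), and had -0.264 in dC27, which did not pass (0.47).

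The count was 1005 without both dC27 arrays, and 1033 when the spread included that between lines. With each array centred on its median 1451 were higher and 1518 lower. The count was 1747 without VC replicate 1, 1901 without VC replicate 2, 1558 without Col-0 replicate 1 and 1395 against VC alone.

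**Figure D2:**
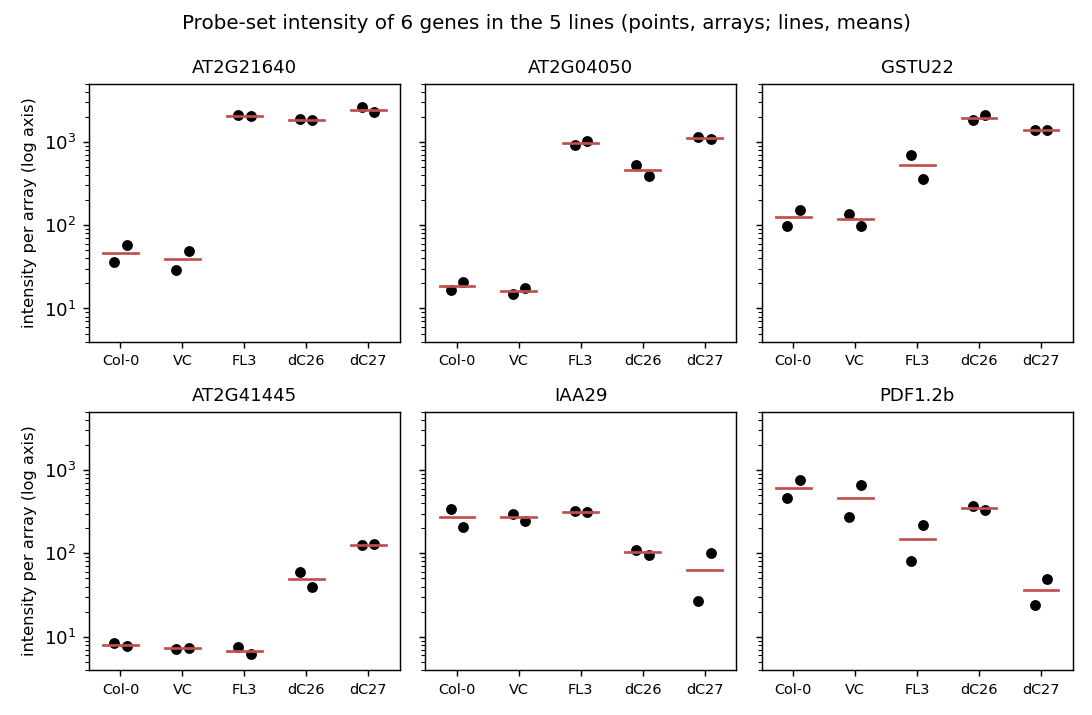
Deposited probe-set intensity on a log axis for 6 genes in Col-0, VC, FL3, dC26 and dC27. Each point is 1 array and each red line the mean of the 2 arrays of a line. AT2G21640 lies at 1846 to 2428 in the 3 TaSIN lines against 38.9 and 46.5 in the controls, AT2G41445 is raised in dC26 (49.8) and dC27 (127) but not in FL3 (6.81), and PDF1.2b is lowest in dC27 (36.5).

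The responses to the 2 forms of TaSIN overlapped. Of the probe sets past the threshold in FL3, 542 were also past it in the dC lines with the same sign, 448 raised in both and 94 lowered in both, and 0 had opposite signs (limma in both contrasts). Independent lists of these sizes would share 41.4. Simulated unchanged groups compared with the same controls shared 0.02 on average and at most 1. Where nothing changes few probe sets pass, so this simulated count cannot show how far shared controls raise the overlap. AT2G21640, AT2G04050, AT2G18190, AT2G20720, AT5G51440 and AT2G32020 were among the 10 largest named rises in both contrasts, and AT1G19540 and AT1G72060 among the 10 largest named falls. Across probe sets, which are not independent replicates, the log2 changes of FL3 and the dC lines correlated with a Pearson coefficient of 0.713 and a Spearman coefficient of 0.621, against 0.407 and 0.372 for simulated unchanged groups. The covariance was 0.0628 against a simulated 0.0079, a difference of 0.0549. With a separate control line for each contrast, 259 probe sets were shared with FL3 set against VC and 277 with FL3 set against Col-0, where independent lists would share 18.0 and 13.1, and the Pearson coefficients were 0.443 and 0.540. The overlap of 542 fell to 50 or 65 without FL3 replicate 1 or 2, to 255 without VC replicate 1, to 205 without Col-0 replicate 1 and to 347 without Col-0 replicate 2.

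**Figure D3:**
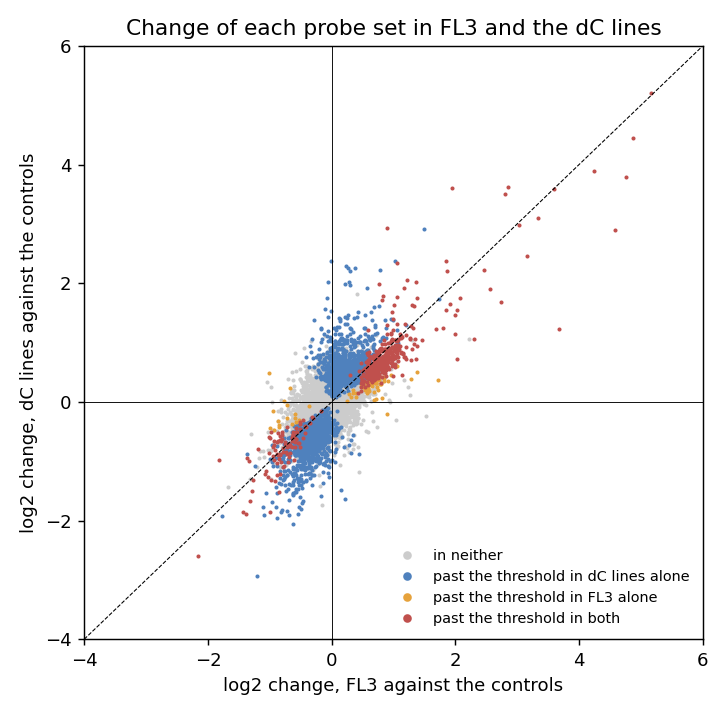
Log2 change of each of 22746 probe sets in FL3 (horizontal axis) and in the dC lines (vertical axis) against the same 4 control arrays, coloured by whether it was past an adjusted p of 0.05 in neither contrast (grey), in the dC lines (blue), in FL3 (orange) or in both (red). The dashed line marks equal change, and the 542 red points have the same sign on both axes.

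The third comparison tested full-length against truncated TaSIN directly. Of 39 probe sets lower in FL3 than in the dC lines, 37 rose in the dC lines against the controls. Between FL3 and the controls 34 did not differ past the threshold, which does not show that they were unchanged. The same FL3 and dC arrays chose the 39, so part of this pattern is built in. AT2G41445 was at 6.81 ± 0.90 in FL3, 49.8 ± 14.8 in dC26 and 127 ± 2.49 in dC27 (SD, n = 2 each), against 7.25 in VC and 8.01 in Col-0. AT1G24430, which encodes an acyltransferase of the BAHD type, was at 48.0 in FL3 and at 240 and 205 in dC26 and dC27, and GSTU22, which also rose in FL3, by 1.94 from the control level of 122, was at 531 in FL3 and at 1955 and 1372.

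The direct test called 47 probe sets, 8 higher and 39 lower in FL3, 27 of them at least 2-fold (limma, Benjamini-Hochberg adjusted p under 0.05), and 2446 had an unadjusted p under 0.05. Among probe sets with exactly 1 gene, the 10 largest differences with lower values in FL3 began, on the log2 scale, with -2.08 ± 0.13 for AT2G41445. Next were -2.03 ± 0.20 for AT1G17960, -1.997 ± 0.26 for AT2G03200, an aspartyl protease gene, and -1.90 ± 0.15 for AT1G24430. They were followed by -1.82 ± 0.29 for AT3G01190, a class III peroxidase gene, -1.67 ± 0.25 for GSTU22 and -1.50 ± 0.20 for AT1G78450. The others were -1.23 ± 0.15 for AT5G14650, a polygalacturonase gene, -1.21 ± 0.17 for AT1G73340, a cytochrome P450 gene, and -1.09 ± 0.10 for AT5G58610. AT1G78450 itself fell in FL3 and rose in dC26, to 207 from 80.7 in the controls. Named probe sets higher in FL3 numbered 4. In 3 of them the arrays of FL3 and the dC lines did not overlap: AT3G60420 by 1.64 ± 0.18, AT1G33420 by 0.89 ± 0.14 and AT1G43590 by 0.68 ± 0.10. The other, AT2G32160, named after its values were seen, was higher by 1.02, with 90.8 in FL3, 88.0 in dC26 and 10.45 in dC27. AT3G60420 stayed near the control level in FL3 (426 against 410 in VC and 350 in Col-0) and fell in dC27 to 59.1, while its other probe set had an intensity of 6.121 or less in all 5 lines and did not pass.

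The auxin response list was higher in FL3 than in the dC lines (camera, adjusted p = 2.2e-06, and adjusted p = 0.10 with an estimated correlation). None of IAA29, GH3.3 and WES1 passed over all probe sets, with log2 differences of 1.85 ± 0.34, 0.91 ± 0.16 and 0.76 ± 0.14 (limma, Benjamini-Hochberg adjusted p = 0.074, 0.074 and 0.082), and all 3 passed adjusted over the list alone. The mitochondrial retrograde list was lower in FL3 (camera, adjusted p = 0.0079, and adjusted p = 0.41 with an estimated correlation), with 0 of 4 members past the threshold over all probe sets and 2 over the list alone, GSTU25 and AT5G09570. For AT2G21640 FL3 and the dC lines differed by -0.04 ± 0.18. The flavonoid and anthocyanin list was lower in FL3 (camera, adjusted p = 0.0093, and adjusted p = 0.32 with an estimated correlation), with 0 members past the threshold over all probe sets and 2 over the list alone, DFR at 10.08 against 15.65 and UF3GT at 20.5 against 31.2, intensities near the lower end of the scale. Of these lists, the mitochondrial one did not pass without FL3 replicate 2 (adjusted p = 0.21) or dC26 replicate 1 (0.051), and the flavonoid one without FL3 replicate 1 (0.074), dC26 replicate 1 (0.051) or dC27 replicate 2 (0.054). The root markers EXPA7, EXPA18 and PYK10 differed by -0.28 ± 0.24, -0.79 ± 0.19 and 0.01 ± 0.21 between FL3 and the dC lines, with EXPA18 past the threshold over the list alone, and the photosynthesis genes by between -0.072 for PSAE-1 and 0.075 for LHCB4.1. The other lists did not pass: cold-regulated genes (camera, adjusted p = 0.066), root markers (0.11), reference genes (0.26), unfolded protein response (0.30), heat shock (0.56), jasmonate response (0.56, with THI2.1 past the threshold over the list alone), cell wall loosening (0.88), senescence (0.88) and photosynthesis (0.89).

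This count moved with single arrays: it was 15 without either VC array, 30 and 28 without Col-0 replicate 1 and 2, 11 and 25 without FL3 replicate 1 and 2, 213 and 21 without dC26 replicate 1 and 2, and 152 and 543 without dC27 replicate 1 and 2. The excess of lower values turned with 2 of these arrays: 120 were higher and 93 lower without dC26 replicate 1, and 14 and 11 without FL3 replicate 2. The count was 2 when the spread included that between dC26 and dC27. Of the 10 lower genes named above, 3 passed whichever array was left out (AT2G41445, AT1G17960 and AT1G24430), while AT3G60420, AT1G33420 and AT1G43590 each failed without some array. Of the 3 lower genes that held, AT1G24430 also passed when the spread included that between dC26 and dC27 (adjusted p = 0.038), and AT2G41445 and AT1G17960 did not (adjusted p = 0.34 and 0.29).

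Each truncated line was also compared with the controls on its own. In dC26 the largest rises were those of AT2G21640 (5.01 ± 0.18), GSTU22 (3.86 ± 0.25), AT2G04050 (3.82 ± 0.14), AT5G51440 (3.24 ± 0.26) and GSTU25 (3.07 ± 0.45), and the largest falls those of WES1 (-1.84 ± 0.14), AT1G10340 (-1.53 ± 0.23), OSM34, an osmotin-like defence protein (-1.43 ± 0.24), AT3G48650 (-1.32 ± 0.28) and AT2G39210 (-1.30 ± 0.23). Of these, 4 of the 5 rises and 1 of the 5 falls, that of WES1, held whichever array was left out. The calls of GSTU25, AT1G10340, OSM34, AT3G48650 and AT2G39210 all ended without dC26 replicate 2. That of AT3G48650 was lost in 13 of 22 settings, with 7 single arrays among them, that of AT2G39210 in 8, with 6 arrays, and that of OSM34 in 5, with 3. In dC27 AT2G21640 (5.401 ± 0.18), AT2G04050 (5.07 ± 0.14), AT2G18190 (4.72 ± 0.25), AT2G32020 (4.29 ± 0.31) and AT2G20720 (4.19 ± 0.21) rose most. The defensin gene PDF1.2b fell in dC27 from 537 to 36.5, a log2 change of -3.34 ± 0.41, and ECS1 (-2.72 ± 0.24), AT3G20340 (-2.62 ± 0.25), AT1G66100 (-2.61 ± 0.21) and AT2G25510 (-2.57 ± 0.31) fell with it.

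In dC26 617 probe sets changed, 435 higher and 182 lower, and in dC27 3797, 1866 higher and 1931 lower (limma, Benjamini-Hochberg adjusted p under 0.05). They shared 444 calls of the same sign and 18 of opposite sign, where independent lists would share 51.1. The arrays of dC27 differed most, with an SD of the log2 difference of 0.415 against 0.293 in dC26. All lines share 1 estimate of the spread, which can understate that of dC27 and so raise the counts that involve it. Simulated unchanged groups shared 0.06 on average, a count kept low because few probe sets pass where nothing changes. The log2 changes correlated across probe sets at 0.607 (Pearson) and 0.526 (Spearman), against 0.333 and 0.303 for simulated unchanged groups, and the covariance of 0.0803 exceeded the simulated 0.0079 by 0.0724. The shared calls numbered 156 and 192 without VC replicate 1 and 2, 156 and 176 without Col-0 replicate 1 and 2, 179 and 177 without FL3 replicate 1 and 2, and 869 and 54 without dC26 replicate 1 and 2. With split controls they were 128 and 228, and the Pearson coefficients 0.482 and 0.442. The dC26 count depended on its second array, at 71 without it and 1727 without the first. It was 197 and 244 without VC replicate 1 and 2, 240 and 223 without Col-0 replicate 1 and 2, 241 and 238 without FL3 replicate 1 and 2, 1010 and 1000 without dC27 replicate 1 and 2, 222 against VC alone, 406 against Col-0 alone and 377 with a replicate block. The dC27 count was 2366 without Col-0 replicate 1 and 2522 against VC alone. Rises outnumbered falls in dC27 without its replicate 1 (1407 and 1331) or 2 (1779 and 1450). The second dC26 array also stood apart in its hybridisation spike-in probe sets, 0.47 on the log2 scale above the mean of the other arrays, and in its ratio of 3' to 5' actin signal, 5.61 against 4.17 to 4.86 elsewhere.

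The direct test between the 2 truncated lines called 670 probe sets, 483 higher and 187 lower in dC26 (limma, Benjamini-Hochberg adjusted p under 0.05). AT1G66100 was at 336 ± 23.1 in dC26 and 20.5 ± 5.39 in dC27, AT5G62360 at 557 and 52.0, the methionine sulfoxide reductase gene MSRB6 at 242 and 14.1, PDF1.2b at 354 and 36.5, and ECS1 at 4581 and 729. AT5G37140 (10.7 and 83.6), AT4G24110 (20.4 and 111), AT2G18190 (208 and 646), AT4G26470 (96.2 and 327) and AT3G44970 (17.8 and 84.0) were lower in dC26. Of these, 4 of the 5 higher and 2 of the 5 lower genes passed whichever array was left out. The call of PDF1.2b ended without either dC26 array, that of AT2G18190 without dC26 replicate 2, and that of AT4G24110 without dC26 replicate 2 or dC27 replicate 1. That of AT4G26470 ended without 1 of 6 arrays: both of VC, both of FL3, dC26 replicate 2 and dC27 replicate 1. The photosynthesis genes LHCB4.1, PSAE-1, PSBY and RCA were higher in dC26 than in dC27 by 0.49, 0.61, 0.65 and 0.50, none past the threshold over all probe sets (limma, Benjamini-Hochberg adjusted p = 0.069, 0.058, 0.067 and 0.086) and all 4 past it over the list alone. The count was 379 and 377 without VC replicate 1 and 2, 361 and 359 without FL3 replicate 1 and 2, 109 without dC26 replicate 2, 412 and 1448 without dC27 replicate 1 and 2, 446 with a replicate block and 142 without both dC26 replicate 2 and dC27 replicate 1. The excess of higher values in dC26 turned without dC27 replicate 2, with 671 higher and 777 lower, and shrank without dC26 replicate 1, with 452 and 391.

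The 2 control lines were compared as a background for the other comparisons. AT4G20420 was at 41.7 ± 4.44 in Col-0 and at 6.91 ± 0.37 in VC, a log2 difference of -1.33 ± 0.10, and lay between 7.64 and 10.5 in the TaSIN lines. AT1G02813 was at 31.7 ± 9.57 in VC and 8.51 ± 1.07 in Col-0, a call that ended with any 1 of 6 arrays left out. Altogether 6 probe sets differed, 5 higher and 1 lower in VC (limma, Benjamini-Hochberg adjusted p under 0.05), 1594 had an unadjusted p under 0.05, and 0 of the 12 gene lists passed the set test. AT2G21640 differed by -0.19 between VC and Col-0 and AT2G04050 by -0.09. The count was 15 without VC replicate 1, 2 without either dC26 array, and 48 and 45 without dC27 replicate 1 and 2, arrays that enter this contrast through the shared estimate of the spread. Without Col-0 replicate 1 more were lower than higher in VC (5 and 2), and without Col-0 replicate 2 all 6 were.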

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

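The tests of shared controls, of the vector, of single arrays, of root tissue and of a stronger response were written down before their results were seen. The reading of the root markers was changed afterwards, because only 1 of the 3, PYK10, has a mean intensity over 100, and markers near the floor exclude nothing.

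FL3 and the dC lines changed 542 probe sets in the same direction. The controls they share do not account for all of this overlap. With separate control lines 259 and 277 were shared, at least 14.4 times the count of independent lists. Both contrasts still used the same estimate of the spread, which independent lists do not allow for. A part due to the shared controls was not excluded. The empty-vector line did not show the shared changes. Over these probe sets VC minus Col-0, signed by the shared direction, had a median of 0.001 (bootstrap interval -0.011 to 0.018). The limit was 0.195, set from a median change of 0.781 in FL3. VC is 1 line, so other insertions or levels of the vector were not tested. The labels name 0 batches of growth or hybridisation, so no batch was tested.

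The 2 lines with truncated TaSIN differed from each other at 670 probe sets, by a direct test, and dC27 changed 3797 probe sets against 617 in dC26. The spread shared by all lines can understate that of dC27, whose arrays differed most, so part of its larger count may come from this. One poor dC27 array is argued against by the count of 2738 or 3229 with 1 of them left out, although dC26 rested on its second array (71 without it, 1727 without the first). For probe sets called in FL3, a stronger form of its response in dC27 is consistent with the data: of 500 probe sets raised in FL3, 93.4% were higher in dC27 than in dC26, and of 111 lowered in FL3, 90.09% were lower, where 50.2% of all probe sets were higher in dC27. It does not cover the whole difference: 18 probe sets changed with opposite signs in dC26 and dC27, among them AT5G62360 (log2 change 1.88 and -1.215) and MSRB6 (2.05 and -1.04), and ECS1 changed by -2.72 in dC27 with -0.325 in FL3. A different share of root tissue in dC27 stays open: the root markers had a median dC27 minus dC26 of -0.15, with EXPA7, EXPA18 and PYK10 at -0.15, -0.19 and 0.44, while the 4 photosynthesis genes had -0.556.

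FL3 and the dC lines differed at 47 probe sets by a direct test, 39 of them higher in the dC lines. The excess in this direction turned with single arrays left out: 93 of 213 were higher in the dC lines without dC26 replicate 1, and 11 of 25 without FL3 replicate 2. A larger share of root tissue in the dC arrays cannot be told apart from an effect of the truncation: the root markers had a median FL3 minus dC of -0.281, but EXPA7 and EXPA18 lie near the floor and PYK10, at 3186 in FL3 and 3158 in the dC lines, was alone above it. FL3 is a single line, so a difference between the constructs and a difference between lines were not separated.

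The control probe set AFFX-r2-At-U12639_at, which enters no comparison, was bright in every transgenic array and dark in Col-0. It measured 990 and 670.4 in VC, 7556 and 7033 in FL3, 1768 and 1949 in dC26, and 2937 and 3341 in dC27, against 9.06 and 7.197 in Col-0. What this probe set detects is not given in the sources used here.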

How the results depend on the processing

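Alternatives chosen after seeing the data were no pseudocount, leaving out both dC27 arrays, and leaving out dC26 replicate 2 with dC27 replicate 1. All those of the gene families were also chosen then. Calls of named genes, together with the largest changes among probe sets with no gene listed, numbered 125. Of these, 90 could be checked against VC or Col-0 alone and 79 in the 2-group fit. Without the dimmest probe sets 123 could be checked, and in the other settings all. Of the calls checked 0 reversed in any setting, and between 1 (median centring) and 32 (without FL3 replicate 1) were lost. The largest share was lost in the 2-group fit with the spread between lines, 29 of 79. Median centring, quantile normalization and the pseudocounts of 1 and 64 left the 7 counts of changed probe sets within 1.5 times their values, and quantile normalization, the only one of these run on them, left both overlaps so too. The causes of the changes below were not tested, except that a 2-fold minimum counts fewer probe sets by construction. Values near the lower end of the scale, where 34.8% lie below 16, limit what dim probe sets can show.

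With VC alone as the control, 391 probe sets changed in FL3, 1395 in the dC lines, 222 in dC26 and 2522 in dC27. With Col-0 alone the count was 391 in FL3 and 406 in dC26, and 3 gene lists passed in FL3. At least a 2-fold change was seen for 114 probe sets in FL3, 346 in the dC lines, 164 in dC26, 769 in dC27, 27 between FL3 and the dC lines, 262 between dC26 and dC27 and 3 between VC and Col-0. With a replicate block the counts were 30 between FL3 and the dC lines, 377 in dC26, 446 between dC26 and dC27 and 2 between VC and Col-0, and the overlap of dC26 and dC27 was 278, though the replicate numbers pair no samples. Without both dC26 replicate 2 and dC27 replicate 1 the counts were 988 in FL3 and 89 between FL3 and the dC lines. With the same 2 arrays left out they were 182 in dC26, 142 between dC26 and dC27 and 39 between VC and Col-0. Without both dC27 arrays 1005 changed in the dC lines. A 2-group fit gave 1033 in the dC lines and 2 between FL3 and the dC lines. A variance prior without a trend gave 18 between FL3 and the dC lines and 0 between VC and Col-0, and a robust prior 83 and 13. Between VC and Col-0 the limma count was also 0 without the dimmest probe sets and 3 with no pseudocount, where 1594 had an unadjusted p under 0.05. Split controls gave overlaps of 259 and 277 and correlations of 0.443 and 0.540 for FL3 and the dC lines, and 128 and 228 with 0.482 and 0.442 for dC26 and dC27. With an estimated correlation 0 lists passed in FL3, the dC lines and FL3 against the dC lines, and with fry 1 passed in the last.

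Leaving out each array in turn gave counts from 57 to 751 in FL3, 1558 to 3723 in the dC lines, 11 to 543 between FL3 and the dC lines, 71 to 1727 in dC26, 2366 to 4134 in dC27, 109 to 1448 between dC26 and dC27 and 2 to 48 between VC and Col-0, with the lone array assumed to vary like the other lines. The overlap ran from 50 to 601 for FL3 and the dC lines and from 54 to 869 for dC26 and dC27, and the correlations from 0.626 to 0.741 and from 0.477 to 0.644. Gene lists past the test numbered 1 to 3 in FL3, 2 to 4 in the dC lines, 1 to 4 between FL3 and the dC lines and 0 to 1 between VC and Col-0.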

Other observations

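Gene families were chosen after seeing the annotation, and the test of chromosome 2 was chosen after the largest rises were seen. Aldehyde dehydrogenases, which oxidise reactive aldehydes, had lower values as a set in both kinds of TaSIN line at the preset correlation. In the dC lines 4 of 8 fell over all probe sets, ALDH6B2 by 0.83, ALDH2C4 by 0.67, ALDH7B4 by 0.63 and ALDH10A8 by 0.54 on the log2 scale, and 0 rose (camera, adjusted p = 0.021, and adjusted p = 0.48 with an estimated correlation). In FL3 ALDH2C4 fell by 0.88 and the other 7 did not pass (camera, adjusted p = 0.025, and adjusted p = 0.51 with an estimated correlation). With quantile normalization the dC difference kept its direction and did not pass (adjusted p = 0.067), and 0 families passed in the dC lines by camera. Of 11 tau glutathione S-transferases GSTU22, GSTU25 and GSTU23 rose in the dC lines, GSTU26 fell and 7 did not pass. As a set they passed upward by fry (adjusted p = 0.0089) and did not pass by camera (adjusted p = 0.35). Among trichome birefringence-like genes, which act in acetylation of wall polysaccharides, TBL36 (1.03), TBL39 (0.82), TBL37 (0.565) and TBL21 (0.31) rose in the dC lines and 18 of 22 did not pass. Among 47 UDP-glycosyltransferases 5 rose, led by UGT73B4 (1.09), and 2 fell, UGT72E1 (-0.91) and UGT85A4 (-0.61). Neither family passed as a set by camera (adjusted p = 0.40 and 0.75), while by fry the first passed upward and the second did not (adjusted p = 0.027 and 0.39).

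Plastid-encoded ribosomal protein genes differed as a set between the control lines at the preset correlation. All 15 named ones had lower values in VC than in Col-0, from -1.11 for rpl20 to -0.21 for rpl14, with a median log2 difference of -0.43 (camera, adjusted p = 6.4e-10, and adjusted p = 0.30 with an estimated correlation), though 0 of 15 passed alone over all probe sets by limma and 5 over the family alone. Autophagy genes, most of them of the ATG8 family, had a median of -0.365 over 8 genes, with 0 past the threshold by limma over all probe sets, where 1594 had an unadjusted p under 0.05, and 1 over the family alone (camera, adjusted p = 0.00038, and adjusted p = 0.22 with an estimated correlation). The 12 ubiquitin-specific proteases had a median of 0.155 (camera, adjusted p = 0.026, and adjusted p = 0.66 with an estimated correlation). In the dC lines the ribosomal genes had a median of -0.24 against the controls (camera, adjusted p = 0.021, adjusted p = 0.077 with quantile normalization, and adjusted p = 0.90 with an estimated correlation). In FL3 9 plant U-box ubiquitin ligases had a median of -0.34, with a fall of PUB25 by 0.57 (camera, adjusted p = 0.025, and adjusted p = 0.53 with an estimated correlation). Both family calls in FL3 ended without VC replicate 2 or FL3 replicate 2 (adjusted p = 0.06). That of the ribosomal genes in the dC lines ended without VC replicate 2, Col-0 replicate 2, dC26 replicate 1 or dC27 replicate 1 (adjusted p from 0.081 to 0.39), and that of the ubiquitin-specific proteases without VC replicate 1 or either Col-0 array (from 0.088 to 0.48).

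Control probe sets for GAPDH, left out of the tests, were at 1075 ± 18.8 in VC, 1097 ± 255 in Col-0, 1755 ± 420 in FL3, 2213 in dC26 and 2927 ± 592 in dC27 for the 3' end, while those for the 3' end of actin were between 4363 and 4898 in the 5 lines.

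The 4 dC arrays and the 4 control arrays differed at 1033 probe sets in a 2-group fit. Of the 35 splits of these 8 arrays 1, the real one, gave as many, and the highest other gave 1. A split that parts the 2 arrays of a line puts differences between lines into the spread. Its count is lowered by that, so chance cannot be excluded this way. Splits that keep both arrays of each line together number 3, too few for a share under 0.05, with 1033 in the real one and 1 in the highest other.

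Many of the largest rises in FL3 lie on chromosome 2, among them AT2G21640, AT2G04050, AT2G18190 and AT2G20720. The hypothesis that genes of this chromosome rise more often was not borne out: 47 of 287 raised named genes, 16.4%, lie there, against 16.3% of all 13286 (Fisher's exact test, two-sided p = 1). That test took all raised named genes whatever the size of their rise, so it does not address the largest rises by themselves. A further hypothesis was that neighbouring genes rise together in the dC lines. There were 38 pairs of adjacent raised genes in the TAIR10.1 order, such as AT2G18180 and AT2G18190, against a mean of 29.3 in 10000 random draws (permutation p = 0.0627). A p of 0.05 or more had been set beforehand as speaking against this hypothesis. That bound was set wrongly, since a p over a threshold does not show that there is no excess, and 38 lies above the random mean, so the question stays open.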
